A study of Lytechinus variegatus with 12 samples.

How the data were processed

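Whole embryos of the sea urchin Lytechinus variegatus were dissociated at 8 stages, and single-cell RNA was captured with the Chromium Single Cell Chip B kit and the 3' v3 reagents, per the labels' protocols. The 12 samples are 1 library each at 2, 4, 6 and 8 hours post fertilization (hpf) and 2 libraries each at early blastula, mesenchyme blastula, early gastrula and late gastrula. Libraries were sequenced as paired-end reads on an Illumina HiSeq, per the labels' protocols. The deposited matrices hold a UMI (unique molecular identifier) count per gene and cell barcode, made by the authors with Cell Ranger 3.0.2 per the labels and carrying software version 3.1.0 per the file headers. The duplicate libraries of the 4 later stages were joined with the cellranger aggr function, per the labels' protocols; its depth setting is not stated. The suffix of each barcode separates the joined libraries again. Its number was taken as the replicate number to name the libraries, although the order of joining is not stated. The number enters a fit only in the replicate-block alternative, where it pairs libraries of different stages by assumption. The submitters' own downstream steps (Seurat 3.1.4, 2000 variable genes, Harmony, 20 dimensions, resolution 1) left no deposited table and were not used.

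The 8 gene tables list the same 30117 features in the same order. Names appear in the late gastrula table alone, where 19020 features carry a gene name, 2528 a number from another urchin's catalogue and 8569 no name; the names were carried to the other stages by feature identifier. The genome build and the annotation version are not given in the sources used here, so no coordinates are given. The supplied table of another annotation shares no identifiers with these features and was not used. Gene names are printed without their species prefix. Many names are shared by several features (for example Ef1a, Atub13, EhH4_65, Seawi, Alx4, Xrn1_1, Rrm2_1, Btub1, Btub3, Msp130r1, Rpl26, AnL1, Cdt1, Tektin2, Hsp701A, Sna, Tbr and Eve). Each value under such a name is that of a single feature and is uncertain, because reads could split between near-identical copies. Of 4 features named Seawi, 2 hold UMIs, called Seawi a (182 CPM at 2 hpf) and Seawi b (64.0 CPM at 2 hpf).

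Cells with 200 or more detected genes were kept, which left out 1 barcode at 6 hpf and 1 in early gastrula library 2. Each stage was clustered on its own, without batch integration: counts were scaled to 10000 per cell and log transformed, and the 2000 most variable genes gave 20 principal components. A graph of 20 nearest neighbours, with links of shared neighbours under 1/15 removed, was parted with the Leiden method at resolution 1 (seed 1). Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, scikit-image 0.26.0 and matplotlib 3.10.9.

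Clusters were named from marker lists written before the data were examined. A marker counted as raised when its summed level was at least 2 times that of the other cells, with 5 or more UMIs and a one-sided p of 0.025. A cluster took the name of the class with most raised markers if there were 3 or more and no other class had more markers among the 10 leading genes (ranked with 5 added to each CPM, the count per 1e6 UMIs of the library). Ties stayed without a name, and so did clusters with a median UMI count under 1/3 of that of the stage and no own marker among the leading genes. This naming rule was set after the clusters had been seen. A stricter p of 0.001, looked at first, left the early blastula germline-like cluster with 2 raised markers and so without a name. The germline list holds the names for nanos, vasa, seawi, foxy, tudor-domain genes, maelstrom and ovo; the skeletogenic list holds alx1, tbr and the spicule and surface protein genes. Clusters of 2, 4 and 6 hpf are given by number, since some met the rule for classes that do not exist at those hours. Clusters kept out by the rule although they had raised germline or skeletogenic markers included 8 hpf cluster 13 (1.08% of cells, Nan2 and Tdrd5 raised). Others held 3.19 and 3.62% of cells (early blastula cluster 13), 0.371 and 0.258% (early blastula cluster 18), 10.9 and 20.0% (mesenchyme blastula cluster 1), 4.62 and 43.1% (early gastrula cluster 1) and 2.30 and 2.52% (late gastrula cluster 17) of libraries 1 and 2.

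UMIs were summed per library, or per library and class, and tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, robust quasi-likelihood test, Benjamini-Hochberg adjustment, adjusted p of 0.05, statmod 1.5.0). Stage steps compared 2 libraries with 2. Steps up to early gastrula, over all cells or germline-like cells, were contrasts in a single fit of the 6 libraries with a shared spread. The step from early to late gastrula was fitted on the libraries of its 2 stages, so its count comes from an unlike fit. Class contrasts over early blastula, mesenchyme blastula and early gastrula used 6 libraries with the library as a block; late gastrula was fitted on its own with 2. Changes of the germline-like difference between stages were tested as an interaction of class and stage. A standard error (SE) is the log2 change divided by the square root of F. Means are CPM ± SD over libraries. DESeq2 1.42.0 was the other test. Gene lists fixed before the data were examined were tested with camera of limma 3.58.1 at its preset correlation of 0.01, and again with an estimated correlation. They cover cell cycle, translation factors, ribosomal proteins, mitochondrial respiration, glycolysis, proteasome, RNA decay and deadenylation, piRNA pathway, histones, biomineralization, skeletogenic regulators, pigment synthesis, endoderm, apical and neural, oral and aboral ectoderm, Wnt and frizzled, Notch, ABC transporters, hatching and early blastula enzymes, cilia, and heat shock and stress. Lists of class contrasts leave out every marker gene, and a list needs 5 tested members. Some names that look like a member and belong to other proteins were dropped (for example Pfkfb4, Ldhd, Cox4nb, Tnni3k and NotchL). Heat shock and stress took every name starting with Hsp or Dnaj, and cilia took every numbered Ccdc name and the tubulin names. Both lists can therefore hold genes of other functions. Cytochrome oxidase assembly factors stayed in, An and AnL stood for the blastula protease, and Clect is a large family. Hatching enzymes is a short name below for the list of hatching and early blastula enzymes, whose members are An and AnL features and He1. No feature is named for mitochondrially encoded genes, Endo16, Ets1, Delta or Span, so these were not tested.

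Named genes followed a rule written before the data were examined: (a) the 8 largest rises and 8 largest falls among named genes with an adjusted p under 0.05, a log2 change of 1 or more, 20 or more CPM in the higher group and one direction in every library pair; (b) up to 2 risen and 2 fallen genes of each list with the smallest adjusted p; and (c) nanos2 (Nan2), vasa, foxy, seawi, alx1, sm50 and msp130 at every stage. From 2 to 8 hpf, part (a) took the 8 largest rises and falls among named genes with 100 or more CPM at either hour. 1 gene that met part (a) for the interaction from mesenchyme blastula to early gastrula is not reported here. For clusters, these genes describe what defines the clusters, since the same UMIs formed them.

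At 2 to 8 hpf there is 1 library per time, so no test was made; intervals are exact 95% Poisson or binomial (Clopper-Pearson) intervals. Intervals and floors (3 counts) cover counting error only. List medians at these hours were set among 10000 random lists of the same size matched on mean level. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs, leaving out cells with fewer. No record says that duplicate libraries came from separate cultures, so p-values rest on the spread between these libraries, which can be technical. The late gastrula class fits have 2 libraries with the library as a block. They take the spread of a gene mostly from other genes, so their p-values do not measure that gene's own spread. Duplicates differed by more than counting noise: the mean chi-square per feature was 2.20, 3.00, 4.10 and 4.01 at the 4 later stages. Across stages the replicate differences of same-numbered libraries had correlations of -0.30 to 0.21 across 4066 features, which are not independent. The sign of each correlation depends on the assumed order of joining, so these values cannot tell whether libraries are paired across stages.

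The fits were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. From early to mesenchyme blastula, 79% of 2-fold and 94% of 4-fold changes were recovered, and 75% and 94% from early to late gastrula. For germline-like against other cells it was 13% and 60% (7.59% false calls), for germline-like against skeletogenic-like cells 58% and 94%, for germline-like cells from early to mesenchyme blastula 31% and 84%, and for the interaction of these stages 7% and 20%. Simulated counts of germline-like against other cells gave 79 calls, against 2454 in the data. The adjusted p is stricter with fewer calls, so these recoveries need not apply to the data.

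Alternatives fixed before the data were examined were DESeq2 size factors in edgeR, the DESeq2 test, no filter beyond 1 count, and 1000 or more detected genes per cell. Resolutions 0.5 and 2, clusters from one random part of the UMIs with tests on the rest, and doublets left out were also fixed then. So were each library left out, thinning to 500 UMIs, and median ratio scaling for the hours. Stage steps, germline-like steps and the interaction also had a replicate block as a fixed alternative, and class contrasts a fit without the library block. Doublets were the highest Scrublet scores at an expected rate of 0.8% per 1000 cells, a rule chosen after the automatic threshold had marked almost no cells in most libraries. Resolution 2 for germline-like steps and the interaction, and other cells matched on UMI count (10 per germline-like cell), were also added after the data had been seen. Where a count of calls under an alternative is set beside the reported one, it counts as the same within 1.5 times.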

Results

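Single-cell RNA counts from whole embryos of the sea urchin Lytechinus variegatus cover 8 stages in 12 libraries: 1 each at 2, 4, 6 and 8 hpf and 2 each at early blastula, mesenchyme blastula, early gastrula and late gastrula. The libraries hold 2812, 936, 5264 and 3708 cells at 2, 4, 6 and 8 hpf, with 6510689, 7598671, 18345022 and 11129051 UMIs. Libraries 1 and 2 hold 4579 and 5808 cells at early blastula (13643474 and 17862355 UMIs) and 3375 and 5786 at mesenchyme blastula (9089096 and 17927153 UMIs). They hold 6683 and 1587 cells at early gastrula (23296251 and 4070172 UMIs) and 12730 and 10659 at late gastrula (28145759 and 20498475 UMIs). The median UMI count per cell was 1043.5 at 2 hpf, 7969.5 at 4 hpf, 3085.5 at 6 hpf and 2164 at 8 hpf, and from 1302 (early gastrula library 2) to 2973 (early gastrula library 1) later. Early gastrula library 2 had 48.1% of its cells under 1000 UMIs against 11.9% in library 1, so shares of cells with a gene are compared after thinning. The genome build is not given.

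How do the transcripts of germline and skeletogenic genes change in the whole embryo over the 8 stages? Nan2, the nanos gene that is kept on in primordial germ cells, stood at 1.84 CPM (0.952 to 3.22, from 12 UMIs) at 2 hpf, 21.6 (18.4 to 25.2) at 4 hpf, 655 (644 to 667) at 6 hpf and 478 (466 to 491) at 8 hpf. It then stood at 431 ± 40.2 CPM at early blastula, 404 ± 26.9 at mesenchyme blastula, 146 ± 12.9 at early gastrula and 152 ± 8.84 at late gastrula (n = 2 libraries each). Vasa, an RNA helicase gene of the germline, stayed between 24.2 CPM at 4 hpf and 38.8 ± 3.24 at mesenchyme blastula. FoxY, a forkhead gene of the small micromere lineage, stood between 1.23 and 1.98 CPM at 2 to 8 hpf, at 0.720 ± 0.226 at early blastula, 1.30 ± 0.340 at mesenchyme blastula, 4.65 ± 1.01 at early gastrula and 5.55 ± 0.566 at late gastrula. Alx1_1, a regulator of skeletogenic cells, went from 1.23 CPM at 2 hpf to 45.1 at 6 hpf, 60.8 ± 3.07 at early blastula and 8.32 ± 1.97 at late gastrula. The single Sm50 feature held almost no UMIs at any stage, and no call was made on it. Its counts cannot tell an absent transcript from one that the gene model misses.

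**Figure D1:**
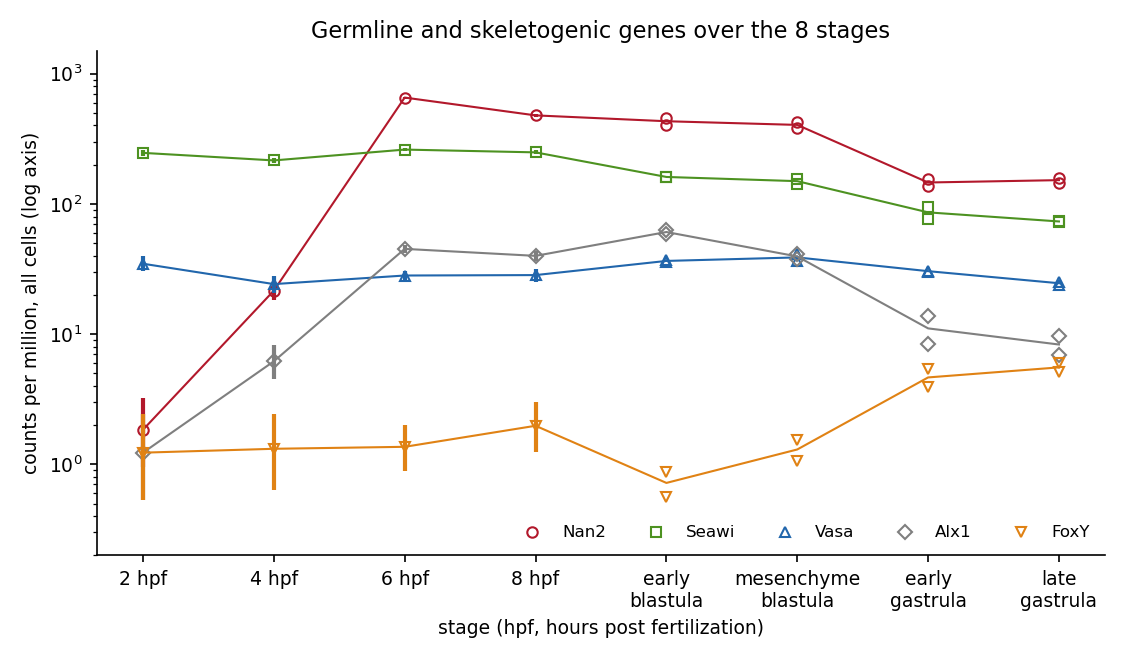
Levels in CPM (log axis) of Nan2, the summed Seawi features, Vasa, Alx1 and FoxY over the 8 stages, with a point per library, a line through the means and 95% Poisson intervals at 2 to 8 hpf. Nan2 goes from 1.84 CPM at 2 hpf to 655 at 6 hpf, while Vasa stays between 24.2 and 38.8.

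Which genes differ most between 2 and 8 hpf? Chz10L went from 0.768 to 2039 CPM (ratio interval 1138 to 8180) and An, a protease gene of the blastula, from 1.08 to 861 (389 to 1993). AnL3 went from 0.768 to 449 CPM (251 to 1803) and Npr3 from 1.08 to 605 (273 to 1401). Hypp_2656 went from 0.614 to 194 CPM (123 to 1162), while Hypp_1813 and PppL_120 began from 2 UMIs each (ratio intervals 178 to 5329 and 164 to 4914). TnfsfL1 had 0 UMIs at 2 hpf and 159 CPM at 8 hpf (ratio of at least 279.9, the lower end of its exact interval). Transcripts that were almost gone by 8 hpf included Ccnr2 (472 to 2.70 CPM, 123 to 260 times lower), TrafA (822 to 9.17, 73.7 to 110 times) and Triol1 (172 to 1.71, 64.2 to 168 times). Hypp_385, Dab2ip, Unk_51, Aimf2l and NekA were also lower at 8 hpf (2.97, 2.70, 4.58, 1.89 and 2.70 CPM from 265, 212, 315, 121 and 172).

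The ratio of Nan2 from 2 to 8 hpf was 259.5 (148 to 503) and that of Alx1_1 lay between 16.3 and 75.7. Vasa had a ratio of 0.818 in CPM (0.687 to 0.975) and a log2 ratio of 0.0639 with median ratio scaling, so its direction depended on the scaling. The Seawi features, piwi genes of small-RNA silencing, stayed at 182 and 184 CPM (Seawi a) and 64.0 and 64.3 CPM (Seawi b). FoxY stood at 1.23 and 1.98 CPM, and Msp130_1, a surface protein gene of skeletogenic cells, at 0.768 and 12.1. All 13 genes of oral and aboral ectoderm with 10 or more UMIs were over 2-fold higher at 8 hpf (median log2 ratio 4.55, percentile 100 among random lists). So were 8 of 9 endoderm genes (3.98, percentile 100), 6 of 7 hatching and early blastula enzymes (6.68, percentile 100). Higher too were 12 of 20 biomineralization genes (1.81, percentile 100), 8 of 12 skeletogenic regulators (2.71, percentile 99.99), 8 of 11 apical and neural genes (2.29, percentile 99.95) and 7 of 12 Wnt and frizzled genes (1.88, percentile 99.85). Ribosomal protein genes (median 0.53, percentile 99.99), mitochondrial respiration (0.67, percentile 99.82) and cilia genes (0.34, percentile 100) moved less. The piRNA pathway had the lowest median, -1.18 (percentile 7.16), with 0 of 12 genes higher and 6 lower. Medians and percentiles were 1.52 and 96.12 for Notch, 0.60 and 94.65 for histones, 0.35 and 91.5 for proteasome, 0.09 and 87.21 for translation factors, 0.38 and 71.05 for pigment synthesis, 0.38 and 59.18 for glycolysis and -0.44 and 33.48 for heat shock and stress. Those of cell cycle (-0.05, percentile 82.23), RNA decay (-0.25, percentile 44.25) and ABC transporters (-0.19, percentile 35.72) turned to 0.31, 0.10 and 0.17 with median ratio scaling.

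Of 2114 named genes with 100 CPM or more at 2 or 8 hpf, 404 were over 2-fold higher and 875 over 2-fold lower at 8 hpf. Scaling matters here: 31.6% of the genes moved were higher in CPM and 41.2% with median ratio scaling, which moved the median log2 ratio of all these genes from -0.55 to -0.20. With 1 library at each hour there was no test, and the intervals leave out differences between embryos and between captures.

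Which genes changed from early blastula to mesenchyme blastula? Among the genes that rose were the endoderm regulator Hnf1 (log2 3.63 ± 0.13 SE, 47.9 ± 7.40 v 3.49 ± 0.0581 CPM), the signal Hh (3.70 ± 0.20) and Wnt7 (2.54 ± 0.32). So did the ectoderm regulators Hox7 (3.11 ± 0.09, 129.9 ± 0.759 v 13.3 ± 1.48 CPM) and IrxA (2.33 ± 0.08, 192 ± 2.05 v 34.0 ± 5.64 CPM). The largest rises also took in Cryz_1 (4.80 ± 0.67), an Ef1a feature (4.30 ± 0.09), Ef1a(Cter) (4.00 ± 0.15), Tmem20_7 (3.48), Slsp_1 (3.35) and Anxa7_1 (2.98). The largest falls were Kcnk18L (-2.30 ± 0.09), the glucose transporter gene Slc2a1 (-2.22 ± 0.07, 45.7 ± 1.35 v 191 ± 7.48 CPM), Hs3st6 (-2.20), Pde8A (-2.12), Tektin2 (-1.92 ± 0.07), DachL (-1.90), Zbed1_3 (-1.90) and Nol1 (-1.85). Alx1_1 fell by 0.78 ± 0.10 on the log2 scale (adjusted p = 7.5e-06), and so did Msp130_1 (-0.38 ± 0.09) and Seawi a (-0.57 ± 0.07). Nan2 fell by 0.26 ± 0.07 on the log2 scale (adjusted p = 0.0077) without the same direction in every library pair. Vasa (-0.06 ± 0.08, adjusted p = 0.58), FoxY (0.64 ± 0.40, adjusted p = 0.2) and Seawi b (0.07 ± 0.13, adjusted p = 0.68) were not called.

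Ribosomal protein genes moved as a group from early to mesenchyme blastula: 53 of 60 rose and 0 fell (54 adjusted over the list alone, median 1.08, camera adjusted p = 1.59e-19, and adjusted p = 0.444 with an estimated correlation), such as Rpl26 (1.49 ± 0.05) and Rpl9 (1.49 ± 0.05). No other list passed (adjusted p 0.112 to 0.926). More cilia genes fell than rose (22 risen, 54 fallen of 150, Tektin1_2 -1.50 ± 0.06), and likewise hatching and early blastula enzymes (0 and 4 of 7, AnL4 -1.07, AnL1 -1.004). The piRNA pathway (2 and 5 of 11, Gtsf1 -1.19 ± 0.06, Tdrd5 -0.998), histones (6 and 11 of 21) and cell cycle genes (7 and 12 of 27, Cdt1 -1.65 ± 0.10) also fell more often than they rose. More rose than fell of translation factors (17 and 6 of 31), mitochondrial respiration (25 and 7 of 54), and proteasome genes (11 and 2 of 26). The same held for apical and neural genes (6 and 2 of 11, 8 and 2 adjusted over the list alone, Ac/Sc 1.68 ± 0.15), Wnt and frizzled (7 and 4 of 15), pigment synthesis (5 and 2 of 21) and ABC transporters (13 and 8 of 55, 12 and 7 adjusted over the list alone). Numbers were closer for oral and aboral ectoderm (6 and 6 of 14, Lefty -1.15 ± 0.07, Nodal -0.94 ± 0.06, median -0.06, mean 0.43, camera upward). They were also close for skeletogenic regulators (6 and 7 of 14, Sna 1.01 ± 0.06, Tbr -0.70), endoderm (5 and 4 of 11, Hox11/13b -1.15 ± 0.06) and heat shock and stress (18 and 15 of 54). The others were biomineralization (3 and 5 of 26), glycolysis (2 and 3 of 13), RNA decay (5 and 4 of 19, 6 and 4 adjusted over the list alone) and Notch (1 and 1 of 6, Hey4 rose by 1.46 ± 0.08). In total 6854 of 14325 genes changed (3430 rose, 3424 fell, edgeR), and 4386 with DESeq2.

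Which genes changed from mesenchyme blastula to early gastrula? Chz10L, which had climbed so far by 8 hpf, fell by 3.69 ± 0.06 on the log2 scale (483 ± 25.2 v 6373 ± 401 CPM, adjusted p = 1.2e-18). Nan2 fell by 1.41 ± 0.08 (146 ± 12.9 v 404 ± 26.9 CPM, adjusted p = 7.5e-11), Alx1_1 by 2.03 ± 0.14 (2.7e-09), Vasa by 0.32 ± 0.09 (0.0076), Msp130_1 by 0.29 ± 0.10 (0.018) and Seawi a and b by 0.94 ± 0.08 and 0.53 ± 0.14. FoxY rose by 2.08 ± 0.28 on the log2 scale (adjusted p = 4.7e-06). The largest rises were Abcc9c (4.07 ± 0.32), Fpgs_6 (3.81), Irf4 (3.61), Fpgs_3 (3.52), Vwd/Egf (3.05 ± 0.11), an Atub13 feature (2.99), Pipox_2 (2.94 ± 0.12, 1694 ± 186 v 226 ± 37.2 CPM) and Abcc10 (2.93). The other large falls were Mysm1 (-4.41 ± 0.66), Nol1 (-3.17), NotchL_1 (-3.13), a PksL feature (-2.99), Hif2a (-2.90), Tuba1c (-2.84 ± 0.33) and GrprL (-2.65).

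At this step 51 of 60 ribosomal protein genes rose (53 adjusted over the list alone, median 0.96, camera adjusted p = 9.4e-20, and adjusted p = 0.146 with an estimated correlation). With them rose 20 of 26 proteasome genes (21 adjusted over the list alone, adjusted p = 2.56e-05, Psmd12 0.84), 19 of 31 translation factors (20 adjusted over the list alone, adjusted p = 0.000175) and 25 of 54 mitochondrial respiration genes (26 adjusted over the list alone, adjusted p = 0.00912). With an estimated correlation these 3 lists had an adjusted p = 0.146, 0.146 and 0.64. Hatching and early blastula enzymes fell (6 of 7, median -1.24, adjusted p = 0.0014, and adjusted p = 0.173 with an estimated correlation, AnL1 -1.24, AnL4 -1.17). With an estimated correlation 4 lists had an unadjusted p under 0.05. Among the other lists (adjusted p 0.287 to 0.941), cilia fell more often than rose (24 risen, 47 fallen of 150, Btub1 rose by 2.84 ± 0.09), as did cell cycle (8 and 15 of 27, Cdt1 -1.70) and the piRNA pathway (1 and 5 of 11). Falls also led in Wnt and frizzled (4 and 6 of 15, Wnt7 2.87 ± 0.17, median 0.11, camera downward) and oral and aboral ectoderm (4 and 6 of 14, Nodal -1.28, median -0.09, mean 0.06, camera downward). Endoderm had 5 risen and 4 fallen of 11 (Hnf1 2.33 ± 0.08, Krl -3.75 ± 0.25), skeletogenic regulators 4 and 6 of 14 (Tbr -1.85 ± 0.10), biomineralization 6 and 5 of 26 (Msp130r1 -1.98), and pigment synthesis 7 and 6 of 21 (median -0.25, camera upward). In total 6500 of 14325 genes changed (3245 rose, 3255 fell, edgeR), and 4110 with DESeq2.

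Which genes changed from early to late gastrula? The largest rises were FbsL_2 (log2 2.04 ± 0.07, 459 ± 1.31 v 118 ± 7.58 CPM), Cuzd1L_1 (1.80), Rfxc1l (1.74), St8sia_1 (1.62), Taui1ph1 (1.45), ApobL (1.44), Sat2 (1.42) and eGas (1.41 ± 0.08), with Tph, a gene of serotonin synthesis, at 1.94 ± 0.35. The 7 largest falls were YP30/FascL_5 (-1.97 ± 0.31), Yp303 features (-1.68 and -1.63), Epdmnrp2 (-1.11), an Nk7 feature (-1.09), Scl, a regulator of blastocoelar cells (-1.05 ± 0.08, 35.4 ± 1.26 v 78.3 ± 0.117 CPM), and Astacin4 (-1.001). None of Nan2 (0.14 ± 0.08, adjusted p = 0.35), Vasa (-0.21, adjusted p = 0.24), FoxY (0.22, adjusted p = 0.57), Alx1_1 (-0.14, adjusted p = 0.8), Msp130_1 (-0.17, adjusted p = 0.34) and the Seawi features (-0.29, adjusted p = 0.086 and -0.11, adjusted p = 0.73) was called. Ribosomal protein genes rose again (38 of 61, 0 fallen, 41 adjusted over the list alone, median 0.40, camera adjusted p = 3.74e-13), with mitochondrial respiration (13 of 56, 16 adjusted over the list alone, adjusted p = 0.00511, Atp5c1 0.54 ± 0.06). Both had an adjusted p = 0.558 with an estimated correlation. The proteasome list passed camera upward (adjusted p = 0.0398) with 0 of 27 genes called by edgeR. Endoderm fell (4 of 11, median -0.31, adjusted p = 0.0219, Hnf1 -0.69 ± 0.07, Eve -0.73 ± 0.09). These 2 lists also had an adjusted p = 0.558 with an estimated correlation. Other lists (adjusted p 0.0582 to 0.911) included apical and neural (5 risen, 1 fallen of 11), skeletogenic regulators (0 and 3 of 14) and oral and aboral ectoderm (3 and 0 of 14, Nodal 0.60 ± 0.08). They also included cilia (7 and 4 of 154), Notch (0 and 2 of 6) and hatching enzymes (1 and 1 of 7, median 0.26, mean -0.08). In total 1105 of 14322 genes changed (673 rose, 432 fell, edgeR). It was 573 with DESeq2, 1690 without early gastrula library 2, 571 without late gastrula library 1 and 565 without late gastrula library 2.

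**Figure D2:**
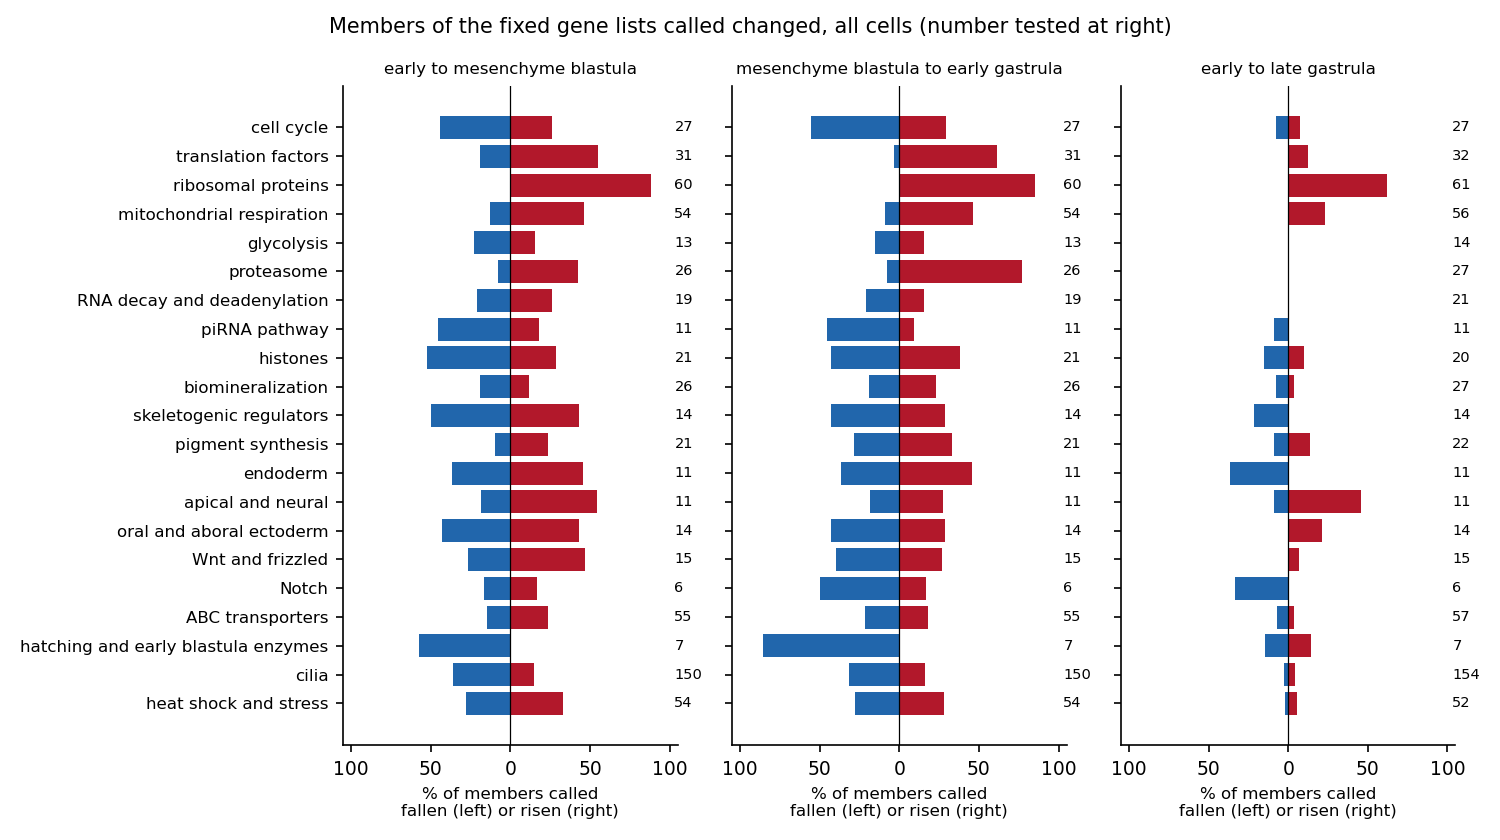
Percent of the tested genes of each list that fell (left) or rose (right) at the 3 stage steps, with the number tested at the right. Ribosomal protein genes rose at each step: 53 of 60, 51 of 60 and 38 of 61.

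How many cells were germline-like and skeletogenic-like? Germline-like clusters held 1.44 and 1.498% of cells at early blastula (mean 1.47 ± 0.0400), 1.42 and 0.951% at mesenchyme blastula (1.19 ± 0.334), 2.30 and 1.51% at early gastrula (1.91 ± 0.560) and 0.550 and 0.694% at late gastrula (0.622 ± 0.102). At 8 hpf the naming rule gave no germline-like cluster; the unnamed cluster 13 (40 cells, 1.08%) had Nan2 at 11666 CPM. Skeletogenic-like cells were 6.98% (6.19 to 7.85) at 8 hpf, 7.32 ± 0.122% at early blastula, 3.70 ± 0.335% at mesenchyme blastula, 1.98 ± 0.224% at early gastrula and 1.24 ± 0.0319% at late gastrula. These shares turn on the cell filter and on clustering. With 1000 or more detected genes per cell the germline-like share was 0.631% at early blastula and the skeletogenic-like share 0.488% at early gastrula and 0.762% at late gastrula. At resolution 2 the early gastrula germline-like share was 0.864% and the mesenchyme blastula skeletogenic-like share 13.2%, and at resolution 0.5 the late gastrula germline-like share was 1.40%.

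Where were the Nan2 transcripts? In germline-like cells Nan2 stood at 10638 ± 194 CPM at early blastula, 4022 ± 181 at mesenchyme blastula, 883 ± 308 at early gastrula and 1908 ± 846 at late gastrula (n = 2 libraries each), holding 19.6 ± 1.21, 8.70 ± 1.04, 12.4 ± 3.06 and 4.99 ± 1.00% of all Nan2 UMIs. Most Nan2 UMIs lay elsewhere. At early blastula unnamed clusters held 36.8 ± 0.0488%, skeletogenic-like cells 19.6 ± 3.02% and endoderm-like cells 12.8 ± 0.883% (558 ± 42.0 CPM), with 1314 CPM in the unnamed cluster 13. Skeletogenic-like cells had 2823 CPM at 8 hpf (40.4% of the UMIs), 1253 ± 305 at early blastula, 842 ± 92.3 at mesenchyme blastula, 69.5 ± 28.3 at early gastrula and 73.5 ± 35.7 at late gastrula. At 6 hpf cluster 8 (394 cells) held 39.9% of Nan2 UMIs and 79.0% of Alx1_1 UMIs. At early gastrula a cluster with muscle and coelomic pouch markers (455 cells) held 32.8% of Nan2 UMIs and 53.9% of those of FoxY. At late gastrula the unnamed cluster 17 (562 cells), kept out by the naming rule although FoxY, Nan2 and Vasa were raised, held 51.0 and 77.9%. The late gastrula germline-like class is therefore a small part of the cells with these genes.

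After thinning to 1000 UMIs, Nan2 was seen in 0.194% of cells at 2 hpf (0.0399 to 0.565, 1262 cells left out), 2.75% at 4 hpf (135 left out), 27.6% at 6 hpf (26.4 to 28.9, 98 left out) and 17.7% at 8 hpf (16.4 to 19.02, 328 left out). Unthinned shares were 9.19% at 4 hpf, 46.7% at 6 hpf, 28.9% at 8 hpf and, as means of 2 libraries, 28.3, 29.6, 14.99 and 9.92% at the later stages. In libraries 1 and 2 the Nan2 share was 15.8 and 17.5% at early blastula (255 and 317 left out), 17.2 and 18.3% at mesenchyme blastula (487 and 1369 left out), 8.05 and 8.13% at early gastrula (798 and 763 left out) and 6.15 and 6.36% at late gastrula (855 and 650 left out). In germline-like cells it was 100 and 96.2% at early blastula (51 of 51 and 75 of 78 cells), 84.6 and 65.3% at mesenchyme blastula, 39.1 and 52.4% at early gastrula and 58.7 and 47.4% at late gastrula. Unthinned these were 100 and 97.7%, 83.3 and 85.5%, 59.1 and 66.7%, and 54.3 and 51.4%. Oral ectoderm-like cells, which should lack Nan2, showed it in 3.92 and 5.44% at early blastula (median UMI 2689 and 2763, against 1576 and 1567.5 in the germline-like cells used), 10.3 and 10.1% at mesenchyme blastula, 5.76 and 3.79% at early gastrula and 5.28 and 4.81% at late gastrula. Skeletogenic-like cells showed it in 75% (168 of 224) at 8 hpf and 44.2 and 46.2% at early blastula. Vasa was seen in 0 and 5.13% of germline-like cells at early blastula and 4.35 and 8.77% at late gastrula, against 2.50 and 3.95% and 4.16 and 3.21% of oral ectoderm-like cells.

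**Figure D3:**
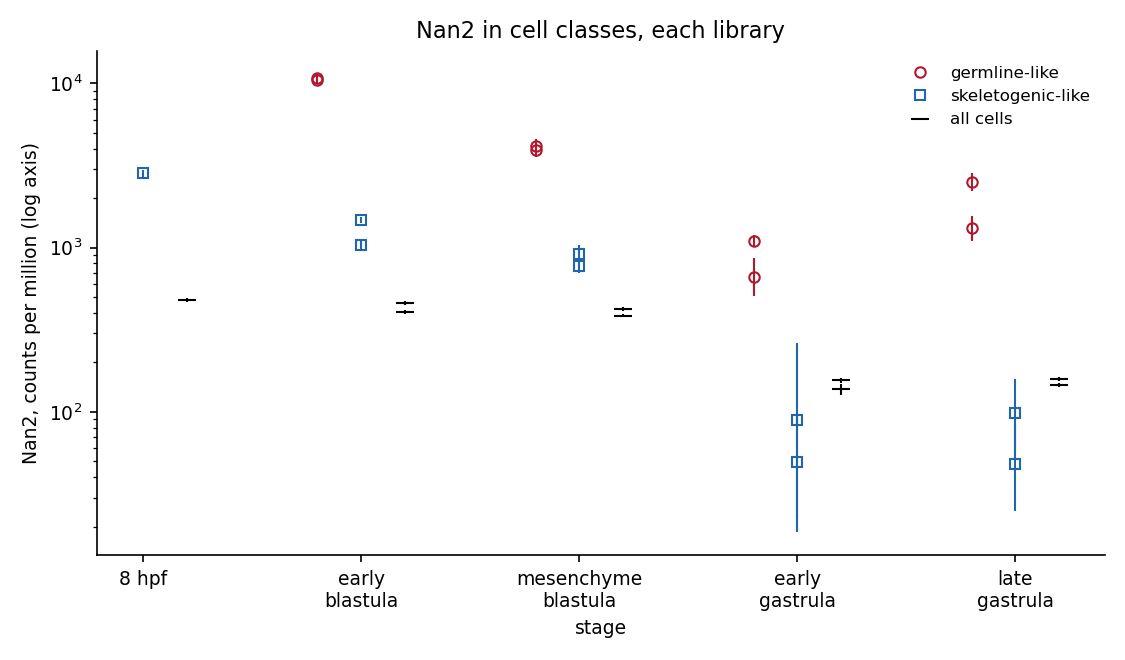
Nan2 in CPM (log axis) in germline-like, skeletogenic-like and all cells of each library from 8 hpf to late gastrula, with 95% intervals. In skeletogenic-like cells it goes from 2823 CPM at 8 hpf to a mean of 73.5 at late gastrula.

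What sets germline-like cells apart from other cells over early blastula, mesenchyme blastula and early gastrula (6 libraries)? The genes that define the clusters were Alx4 (log2 3.46 ± 0.24, 309 ± 80.7 v 21.0 ± 8.59 CPM), CycJ (3.27 ± 0.46), Nan2 (3.23 ± 0.39, 5181 ± 4458 v 284 ± 121 CPM) and Xrn1_1 (2.23 ± 0.40). They also took in Sterol_oxd (2.88 ± 0.35), Serrp14 (2.58 ± 0.31), an EhH4_65 histone feature (2.32 ± 0.20) and PappA1L (2.24 ± 0.42). Lowest were Fpgs_3 (-4.50 ± 0.79), Kcnk18L (-4.23 ± 0.70), Pipox_2 (-3.78 ± 0.29, 67.3 ± 117 v 660.5 ± 834 CPM), Gpr52L_5 (-3.74 ± 0.63), RapL (-3.67 ± 0.58), Cyp2L42 (-3.62 ± 0.71), Btub1 (-3.47 ± 0.43) and Sgarp1 (-3.43 ± 0.50). Msp130_1 was lower (-2.69 ± 0.40). Vasa (-0.60 ± 0.34, adjusted p = 0.22), FoxY (0.16 ± 0.88, adjusted p = 0.92), Alx1_1 (-0.36 ± 0.35, adjusted p = 0.52) and the Seawi features (0.45 ± 0.24, adjusted p = 0.19 and 0.14 ± 0.25, adjusted p = 0.74) were not called, in a fit that recovered 13% of simulated 2-fold changes. The other cells include the early gastrula cluster with muscle and coelomic pouch markers, which held most FoxY UMIs of that stage. Of the deadenylation genes, Cnot1 was higher (1.41 ± 0.26, 126 ± 59.2 v 32.3 ± 6.23 CPM) and Cnot6L lower (-1.71 ± 0.29, 38.2 ± 12.97 v 98.8 ± 18.0 CPM), with Pum, a translational repressor, also lower (-0.96 ± 0.16).

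Cell cycle genes were lower in germline-like cells as a group: 17 of 26 lower and 1 higher (21 and 1 adjusted over the list alone, median -1.02, camera adjusted p = 0.0105, and adjusted p = 0.883 with an estimated correlation). The replication gene Mcm7 (-1.61 ± 0.25) and the cyclin gene Cycb3 (-1.24 ± 0.19) were lower, while Rrm2_1 was higher (0.94 ± 0.31). Cilia genes (6 higher, 48 lower of 134, 7 and 58 adjusted over the list alone, median -0.71, adjusted p = 0.0313, Atub13 -2.47 ± 0.24) and Wnt and frizzled genes (0 and 6 of 13, median -1.01, adjusted p = 0.0313, Sfrp1/5 -2.47 ± 0.32, Dkk3 -2.86 ± 0.53) were lower too, both with an adjusted p = 0.883 with an estimated correlation. Ribosomal protein genes had 0 of 59 called with a median of -0.04 and a mean of -0.07, yet camera placed them upward (adjusted p = 0.0411, and adjusted p = 0.883 with an estimated correlation). The other lists did not pass (adjusted p 0.62 to 0.924): translation factors 0 higher and 7 lower of 29, mitochondrial respiration 2 and 9 of 46 (median -0.20, camera upward) and ABC transporters 1 and 12 of 44. Biomineralization had 0 and 4 of 9, and heat shock and stress 1 and 7 of 45 (median -0.09, camera upward). Histones had 4 and 7 of 19 (median -0.62, camera upward), RNA decay 2 and 2 of 15 (median -0.07, mean 0.13, camera upward) and hatching enzymes 0 and 0 of 6. At resolution 2 hatching enzymes had 5 of 6 lower. With clusters from a random part of the UMIs, camera called none of cell cycle, cilia and ribosomal protein genes (adjusted p = 0.0551, 0.0806 and 0.384). Of 59 ribosomal protein genes 0 were higher and 5 lower there. In total 2454 of 11103 genes differed (624 higher, 1830 lower, edgeR). Scaling with DESeq2 factors moved the median of all genes by 0.11 on the log2 scale and the higher share of calls from 25.4 to 34.5% (828 higher, 1574 lower). Against other cells matched on UMI count, 1958 of 7567 genes differed (750 higher, 1208 lower). The median of all genes was -0.04 there (-0.18 reported), so the excess of lower genes was smaller at matched depth.

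What sets skeletogenic-like cells apart from other cells in the same 6 libraries? The clusters were defined by ApL (log2 7.59 ± 0.29, 393 ± 202 v 1.93 ± 1.02 CPM), Msp130r1 (7.09 ± 0.30), Msp130_1 (7.05 ± 0.30, 1885 ± 1146 v 14.5 ± 9.59 CPM) and Alx1_1 (5.71 ± 0.24, 657 ± 189.6 v 12.3 ± 5.12 CPM). They also took in FcgbpL (6.99 ± 0.29), Mt1_4/MmpL5 (6.98 ± 0.27), Odadc1L (6.61 ± 0.67), C_lectin (6.57 ± 0.34) and CbpdEL (6.53 ± 0.30). Lowest were the neural regulator Isl (-4.93 ± 0.74), Ugt2b34_3 (-3.12 ± 0.47), Bra_1 (-2.85 ± 0.28), Slc46a3 (-2.84 ± 0.38), Ankrd53 (-2.81 ± 0.52), AnL3 (-2.76 ± 0.27), AnL1 (-2.74 ± 0.37) and Six3 (-2.71 ± 0.31). Nan2 (0.84 ± 0.49, adjusted p = 0.26), FoxY (-0.82, adjusted p = 0.58) and the Seawi features (-0.09, adjusted p = 0.79 and -0.34, adjusted p = 0.24) were not called, and Vasa was lower (-0.88 ± 0.27, adjusted p = 0.0088). Biomineralization genes (7 higher, 2 lower of 12, 8 and 2 adjusted over the list alone, median 1.71, camera adjusted p = 0.000907, and adjusted p = 0.194 with an estimated correlation, Col4a2 3.37 ± 0.22) were higher. So were skeletogenic regulators (3 and 1 of 8, adjusted p = 0.0179, and adjusted p = 0.505 with an estimated correlation, Sna 4.34 ± 0.43). Cilia genes (12 and 68 of 134, 12 and 71 adjusted over the list alone, median -0.79, adjusted p = 0.0026, and adjusted p = 0.72 with an estimated correlation, Tektin2 -1.91 ± 0.21) were lower. So were hatching enzymes (0 and 6 of 7, 0 and 7 adjusted over the list alone, median -2.34, adjusted p = 0.0386, and adjusted p = 0.357 with an estimated correlation). Skeletogenic-like cells were shallow in mesenchyme blastula library 2 (median 1283.5 UMIs against 2955.5 in the library) and at early gastrula (754.5 against 2973 and 544 against 1302), with up to 10.96% called doublets, and no comparison matched on UMI count was made for this class. Other lists (adjusted p 0.0802 to 0.637) included cell cycle (0 and 8 of 26, Wee1 -1.94 ± 0.25), Wnt and frizzled (1 and 8 of 14, Wnt9 3.67 ± 0.43), glycolysis (1 and 4 of 10) and Notch (2 and 2 of 6, Hes -2.05 ± 0.21). In total 3839 of 11290 genes differed (1501 higher, 2338 lower, edgeR).

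How do germline-like cells differ from skeletogenic-like cells? Higher in germline-like cells were Hairy2/4 (log2 3.37 ± 0.52), Alx4 (3.17 ± 0.31), the base-repair gene Nthl1 (3.10 ± 0.47), SoxE (3.08 ± 0.54), Z447 (3.06 ± 0.59), Wdr76 (3.04 ± 0.36), Serrp14 (3.02 ± 0.38) and Sterol_oxd (2.91 ± 0.47). Nan2 was higher by 2.65 ± 0.24 (5181 ± 4458 v 722 ± 556 CPM, adjusted p = 1.7e-06). Lower were Msp130_1 (-7.81 ± 0.35), Astacin1 (-7.77 ± 0.58), Msp130L (-6.89 ± 0.41), Msp130r1 (-6.82 ± 0.37), CbpdEL (-6.79 ± 0.47) and Alx1_1 (-4.44 ± 0.30). Tpte, C_lectin and Vps13d had 0 UMIs in germline-like cells against 156 ± 99.1, 73.2 ± 71.3 and 46.2 ± 22.1 CPM, so no fold is given. Seawi stood higher without a call (0.65 ± 0.27, adjusted p = 0.079 and 0.64 ± 0.26, adjusted p = 0.07). Biomineralization genes were lower (4 of 5, 5 adjusted over the list alone, median -3.73, camera adjusted p = 0.000698, and adjusted p = 0.112 with an estimated correlation). Ribosomal protein genes were higher (7 of 51, 0 adjusted over the list alone, median 0.26, adjusted p = 0.01, and adjusted p = 0.705 with an estimated correlation, Rpl13 0.62 ± 0.17). Translation factors (0 higher, 6 lower of 22), cilia (5 and 15 of 59, Ccdc55 1.41 ± 0.23, Axndhc4h -4.35 ± 0.61), skeletogenic regulators (0 and 3 of 6, Hhex -3.00 ± 0.37) and heat shock and stress (3 and 5 of 27) did not pass (adjusted p 0.191 to 0.502). Ccdc55 is in the cilia list by the form of its name alone. In total 1376 of 3770 genes differed (625 higher, 751 lower, edgeR), and 776 with clusters from one random part of the UMIs and tests on the rest.

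**Figure D4:**
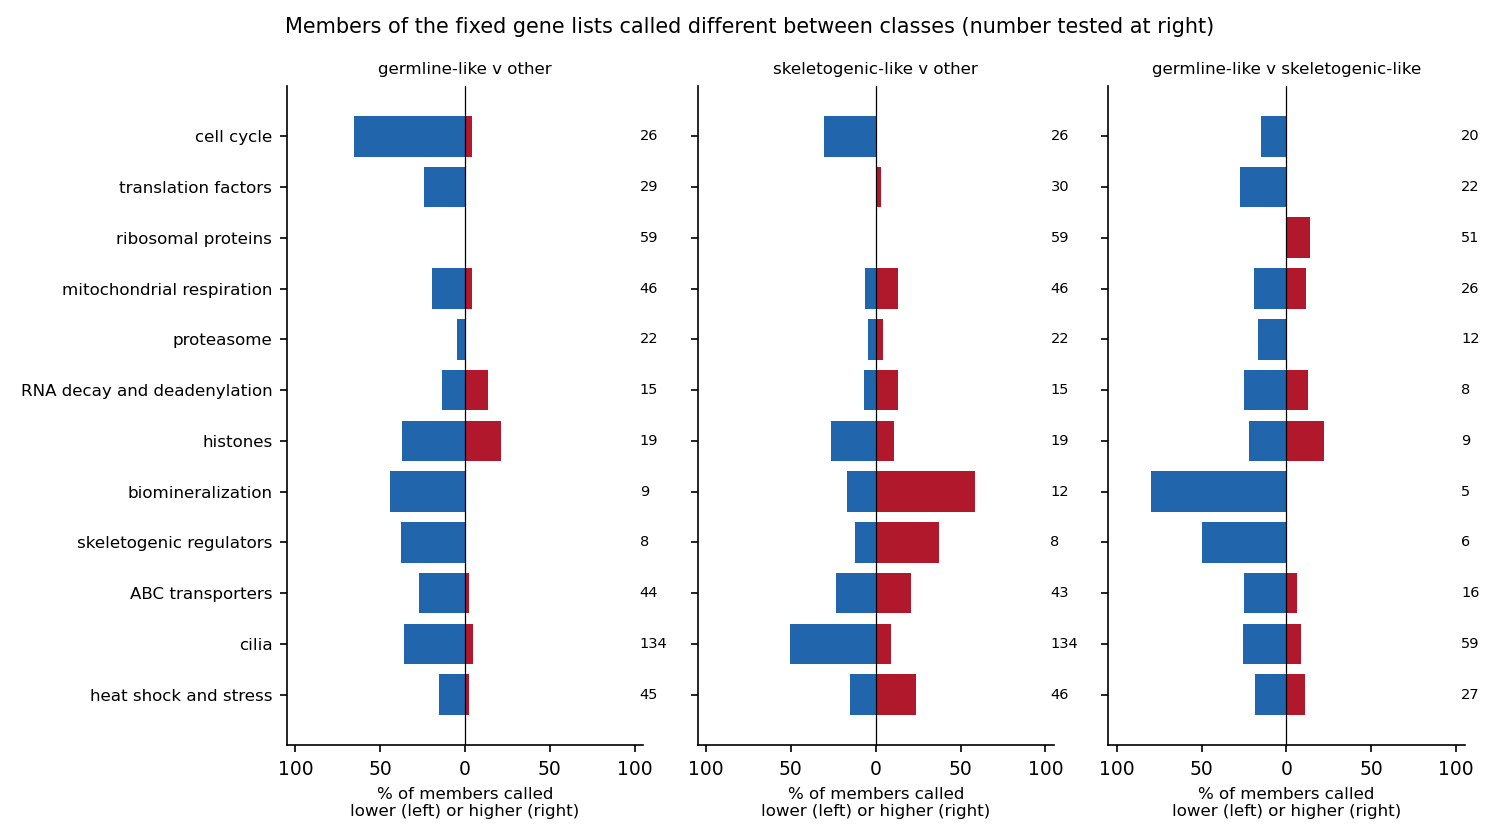
Percent of the tested genes of each list that were lower (left) or higher (right) in germline-like v other, skeletogenic-like v other and germline-like v skeletogenic-like cells, with the number tested at the right. Of cell cycle genes 17 of 26 were lower in germline-like cells and 8 of 26 in skeletogenic-like cells.

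Do the class differences hold at late gastrula (2 libraries)? The germline-like cells were defined by Alx4 features (log2 4.85 ± 0.31, 369 ± 37.5 v 8.34 ± 0.551 CPM, and 4.77 ± 1.08). They were also defined by Maf (4.405 ± 0.51), CycJ (4.397 ± 1.09), Aspapd (3.88), Sterol_oxd (3.65), Z423 (3.62) and MaelL, a gene of the piRNA pathway (3.58 ± 0.42, 169 ± 27.2 v 9.21 ± 2.03 CPM). Nan2 was higher (3.07 ± 0.13, 1908 ± 846 v 145 ± 10.2 CPM), and so was Seawi b (1.33 ± 0.30, adjusted p = 0.00018). Vasa (1.01 ± 0.47, adjusted p = 0.15), FoxY (0.82, adjusted p = 0.78), Alx1_1 (1.46, adjusted p = 0.25) and Seawi a (-0.07, adjusted p = 0.96) were not called. The other cells include the unnamed cluster 17, where FoxY, Nan2 and Vasa were raised. Missing calls of Vasa and FoxY therefore do not show that germline-like cells lack them. Slsp_1, Tmem26_5, Hh, Slc44a2, Odadc2L1, Tmem20_7, HpcaL1 and Ptprorph2 had 0 UMIs in germline-like cells against 127 ± 12.7, 115 ± 4.41, 113 ± 0.953, 88.7, 87.2, 85.4, 75.4 and 68.9 CPM. A count of 0 allows up to 32.1 and 28.3 CPM in these libraries. By camera 0 of 17 lists passed (adjusted p 0.257 to 0.94, 1 at unadjusted p under 0.05, and 0 with an estimated correlation). The median log2 difference of all genes in this fit was -0.57 (-0.41 with DESeq2 factors), and 38 of 59 ribosomal protein genes, 42 of 143 cilia genes (2 higher), 7 of 26 cell cycle genes (Cdk1 -1.73 ± 0.25) and 6 of 15 Wnt and frizzled genes were lower, which is no group result beside that offset. In total 1911 of 12284 genes differed (375 higher, 1536 lower, edgeR). It was 800 with DESeq2, 1011 at resolution 2, 1205 with doublets left out and 247 with clusters from one random part of the UMIs; at resolution 0.5, 127 of the calls had the other sign.

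Late gastrula skeletogenic-like cells were defined by ApL (log2 10.01 ± 0.25), Cp (9.17), Kirrel2L (9.17), Msp130r1 (8.88 ± 0.29), Msp130_1 (8.66 ± 0.15, 3574 ± 475 v 8.58 ± 0.321 CPM), FcgbpL (8.44), C_lectin (8.43) and the spicule gene Sm37 (8.41 ± 0.22), with Alx1_1 at 5.12 ± 0.30. Nan2 was lower there (-1.16 ± 0.28, 73.5 ± 35.7 v 153 ± 8.58 CPM, adjusted p = 0.00044). Cell cycle genes (16 of 26 lower, 17 adjusted over the list alone, median -1.08, camera adjusted p = 0.0102) and ribosomal protein genes (47 of 60 lower, 49 adjusted over the list alone, median -0.67, adjusted p = 0.0102) were lower. With an estimated correlation neither passed (adjusted p = 0.778 for both). Skeletogenic regulators were higher (3 of 8, 4 adjusted over the list alone, adjusted p = 0.0192, and adjusted p = 0.778 with an estimated correlation). These cells were shallow (median 802 and 683 UMIs against 2033 and 1721 in their libraries), 31.7 and 23.1% of them were called doublets, and no comparison matched on UMI count was made for this class. Biomineralization genes, 6 of 14 higher, had a median of 1.001, a mean of -0.20 and an upward camera result that did not pass (0.108). In total 1870 of 12419 genes differed (915 higher, 955 lower, edgeR), and 1136 with DESeq2 and 1200 with clusters from one random part of the UMIs. DESeq2 factors in edgeR moved the median of all genes by 0.12 and the higher share from 48.9 to 59.3% (998 higher, 686 lower). Against skeletogenic-like cells, late gastrula germline-like cells were higher in Nan2 (4.42 ± 0.25, adjusted p = 2.9e-59), Seawi b (2.38 ± 0.50, adjusted p = 9.1e-06), Kiaa1147 (4.08), Alx4 (4.05), Gkap1 (3.94 ± 0.44), MaelL (3.69) and Maf (3.67), and lower in Msp130_1 (-7.77 ± 0.29) and Alx1_1 (-3.06 ± 0.49). Ribosomal protein genes were higher (34 of 48, 37 adjusted over the list alone, median 0.44, adjusted p = 0.00209) and biomineralization genes lower (5 of 5, median -4.96, adjusted p = 0.00209), neither passing with an estimated correlation (smallest adjusted p = 0.713). There 1444 of 2613 genes differed (627 higher, 817 lower, edgeR), 492 with DESeq2 and 730 with clusters from one random part of the UMIs. Leaving out a library leaves no residual degrees of freedom here, so that was not done. The late gastrula class contrasts were not among the fits tested on simulated counts. Their very small p-values are therefore no measure of the spread of a gene between the libraries.

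What changed inside germline-like cells from early to mesenchyme blastula (2 libraries v 2)? Nan2 fell by 1.38 ± 0.17 on the log2 scale (4022 ± 181 v 10638 ± 194 CPM, adjusted p = 1.7e-07). The RNA-binding gene Cugbp1 rose by 4.37 ± 0.67 (173 ± 35.1 v 8.22 ± 1.96 CPM), with Dab2ip (3.06), Brn1_2_4 (2.73), P16 (2.70 ± 0.40), FReD (2.48), Kiaa1598L (2.46), P19 (2.38 ± 0.31) and Nk2_2 (2.32 ± 0.71). The largest falls were Lrr/Gpcr_9 (-3.56 ± 0.92), Ccdc83 (-3.55 ± 0.81), the cyclin gene Cycb (-2.45 ± 0.77), Rrm2_1 (-2.43 ± 0.65), Axndhc10h (-2.40 ± 0.50), Lrrc23 (-1.97 ± 0.53), C1orf173L (-1.96 ± 0.37) and Hp_Loc200403L_1 (-1.84 ± 0.48), and Cdk1 fell by 1.34 ± 0.29. Ribosomal protein genes rose (37 of 48, 41 adjusted over the list alone, median 0.86, camera adjusted p = 1.62e-17, and adjusted p = 0.324 with an estimated correlation). Cilia genes fell (8 of 45, 9 adjusted over the list alone, median -0.50, adjusted p = 0.00295, and adjusted p = 0.3 with an estimated correlation, Tektin2 -1.73 ± 0.34). Cell cycle had 3 risen (Mcm6 1.32 ± 0.34) and 4 fallen of 13; the Seawi features were not called (-0.05, adjusted p = 0.95 and 0.18, adjusted p = 0.87). In total 209 of 2653 genes changed (121 rose, 88 fell, edgeR), 92 with DESeq2, 71 with no filter beyond 1 count, 116 without early blastula library 1 and 127 without mesenchyme blastula library 2.

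From mesenchyme blastula to early gastrula Nan2 fell again in germline-like cells, by 1.95 ± 0.18 on the log2 scale (883 ± 308 v 4022 ± 181 CPM, adjusted p = 5.6e-11). With it fell Brn1_2_4 (-4.59 ± 0.83), Ksr2 (-3.82 ± 0.90), Taui1ph1 (-3.22 ± 0.52), Eea1 (-2.32 ± 0.55), ClvhH1 (-2.29 ± 0.49), Sfrs6 (-2.10 ± 0.36) and Serrp14 (-1.95 ± 0.42). The largest rises were FoxG (5.36 ± 0.73), an Ef1a feature (3.39 ± 0.50), TnfsfL1 (3.36 ± 0.70), Hox7 (3.26 ± 0.69), An (3.11 ± 0.42), Ccdc83 (3.07 ± 0.82) and eGas (3.00 ± 0.73); Sat2_5 went from 0 UMIs to 106 ± 31.5 CPM. Oral and aboral ectoderm genes (4 of 8, 6 adjusted over the list alone, camera adjusted p = 2.31e-05, and adjusted p = 0.163 with an estimated correlation) rose. So did cilia genes (11 of 45, 12 adjusted over the list alone, adjusted p = 0.00293, and adjusted p = 0.163 with an estimated correlation) and ribosomal protein genes (10 of 48, 15 adjusted over the list alone, adjusted p = 0.000128, and adjusted p = 0.451 with an estimated correlation). In total 337 of 2653 genes changed (239 rose, 98 fell, edgeR), 108 with DESeq2, 213 with no filter beyond 1 count, 217 without mesenchyme blastula library 1 and 187 without early gastrula library 1. At resolution 2 it was 96 (33 rose, 63 fell), and 80 of the 337 genes had the other sign. Of the oral and aboral ectoderm list 3 genes could be tested there, 0 were called and the median was -0.21 (1.16 reported), so ectoderm-like cells in the early gastrula cluster are not excluded as the source of that rise. The cilia list no longer passed there (1 risen, 1 fallen of 44, median 0.0997, adjusted p = 0.885). Ribosomal protein genes still rose at resolution 2 (8 of 49, median 0.56 against 0.43 reported, camera adjusted p = 6.9e-11, and adjusted p = 0.89 with an estimated correlation). Btub3 went from 1.89 ± 0.25 to -0.33 and Atub13 from 1.51 ± 0.21 to -0.80, while Nan2 kept its fall. At early gastrula a cluster with muscle and coelomic pouch markers held more of the Nan2 UMIs than the germline-like cells did. A change in which cells took the germline-like name is therefore not excluded as a source of the Nan2 fall.

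Did the difference between germline-like and other cells itself change? From early to mesenchyme blastula Nan2 lost part of its lead (interaction log2 -1.38 ± 0.22, 3.42 ± 0.02 v 4.91 ± 0.18 over other cells, adjusted p = 9.5e-07). P16 (2.89 ± 0.44) and P19 (2.83 ± 0.35), genes of biomineralizing cells, FReD (3.10 ± 0.55) and Eve (2.65 ± 0.48) moved upward relative to other cells, and Hox7 downward (-4.26 ± 1.00). Msp130, its 2 features summed, was also more frequent in oral ectoderm-like clusters (2.13 CPM in the early blastula cluster, 13.1, 10.9 and 18.1 in those of mesenchyme blastula), so RNA from other cells is not excluded for P16 and P19. In total 41 of 11103 genes changed (25 upward, 16 downward, edgeR), 19 with DESeq2 and 23 with no filter beyond 1 count. The count was 27 at resolution 2, 13 without early blastula library 1, 18 without early blastula library 2, 27 without mesenchyme blastula library 1 and 7 without mesenchyme blastula library 2. By camera 0 of 16 lists passed (adjusted p 0.282 to 0.927, 2 at unadjusted p under 0.05, and 0 with an estimated correlation). From mesenchyme blastula to early gastrula 569 genes changed (515 upward, 54 downward, edgeR), 259 with DESeq2. All 6 genes of the hatching and early blastula enzyme list moved upward (An 5.06 ± 0.42, camera adjusted p = 0.000976, and adjusted p = 0.384 with an estimated correlation). So did 25 of 134 cilia genes (30 adjusted over the list alone, adjusted p = 0.00488, Tektin2 2.80) and 3 of 26 cell cycle genes (6 adjusted over the list alone, adjusted p = 0.0153, Cycb 3.19), with an adjusted p = 0.476 and 0.384 with an estimated correlation. Downward moved 5 of 59 ribosomal protein genes (10 adjusted over the list alone, adjusted p = 0.000231, and adjusted p = 0.668 with an estimated correlation, Rpl28 -0.84). At resolution 2, where the early gastrula germline-like cells were 77 in place of 178, the count was 16 (8 and 8) and 185 of the 569 genes had the other sign. None of the 4 lists passed camera there: cell cycle (median 0.0845, adjusted p = 0.96), cilia (-0.11, adjusted p = 0.96), hatching enzymes (1.22, adjusted p = 0.203) and ribosomal protein genes (-0.57, adjusted p = 0.057). The reported medians were 0.81, 1.06, 4.97 and -0.39, so that of ribosomal protein genes did not shrink. It was 323 without mesenchyme blastula library 1, 275 without mesenchyme blastula library 2 and 245 without early gastrula library 1, and DESeq2 factors moved the median of all genes by -0.18. Nan2 was not called at this step (-0.41 ± 0.24, adjusted p = 0.46).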

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

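Nan2 outside the germline-like cluster: both tests here, for free RNA and for doublets with germline-like cells, were chosen only after the result was seen. Their bounds were also set then, so neither explanation is called excluded. Free RNA alone would leave skeletogenic-like cells near the level of the whole library. At early blastula they had 2.57 and 3.19 times its Nan2 CPM. The lower ratio of 2.57 argues against free RNA as the whole source for the class. The class joins 2 clusters at early blastula, which were not tested apart. Doublets with germline-like cells would give a share of Nan2-positive skeletogenic-like cells near the expected doublet rate. The share was 12.1 and 9.95 times that rate, and the lower ratio of 9.95 argues against doublets as the whole source. No biological explanation was tested, and both ratios concern skeletogenic-like cells alone, which held 19.6% of Nan2 UMIs at early blastula against 36.8% in unnamed clusters and 12.8% in endoderm-like cells.

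Lower cell cycle and cilia genes in germline-like cells: the test with other cells matched on UMI count was chosen only after the result was seen. Germline-like cells had fewer UMIs in 5 of the 6 libraries (median 1449.5 against 2481 in other cells of early blastula library 1) and more in early gastrula library 2 (3071 against 1231), yet against matched cells the cell cycle median was still -0.82 (reported: -1.02), which excludes a lower UMI count as the whole cause. With clusters from one random part of the UMIs and tests on the rest it was -1.09 (quartiles -1.61 to -0.83, reported -1.38 to -0.63) with again 17 of 26 genes lower, which excludes the use of the same UMIs as the cause of the lower median. The list call was lost there (adjusted p = 0.0551, and 0.0806 for cilia) while the median of all genes moved from -0.18 to -0.29. Slower division of these cells is a hypothesis that was not tested. With an estimated correlation in camera the reported list did not pass (adjusted p = 0.883).

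Rise of blastula protease and hatching enzyme genes in germline-like cells from mesenchyme blastula to early gastrula: the test at resolution 2 was chosen only after the result was seen. The median interaction of 4.97 went to 1.22 on the log2 scale, between the bounds of 1 and 3 set for a call, so a mixed early gastrula cluster cannot be told from a real change. At resolution 2 the germline-like cells were 77 in place of 178 and 0 of the 6 genes were called. Inside germline-like cells 1 gene of the list could be tested there, with a log2 change of 0.37 and 0 called. The reported median over 3 genes was 3.11. The list fell over all cells at this step, so an upward interaction alone need not be a rise inside germline-like cells. Other cells caught in the cluster may account for most of the rise.

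Class labels were also swapped inside libraries for the 3 contrasts over 6 libraries, which allows 32 splits and a smallest share of 1 of 32 (0.03125). The real labels gave the highest count in each contrast (1 of 32): 2454 against at most 32 for germline-like v other cells, 3839 against at most 2635 for skeletogenic-like v other cells, and 1376 against at most 305 for germline-like v skeletogenic-like cells. The split with 2635 swapped early gastrula library 2 alone, which has few skeletogenic-like cells. The clusters were formed on the UMIs tested, which favours the real labels from the start, so this count cannot tell whether the grouping arose by chance.

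The germline-like difference changed for 41 genes from early to mesenchyme blastula. Upward moved Fog (4.66 ± 1.19, 2.82 v -0.70 over other cells), Ablim1 (4.43 ± 1.17, 0.29 v -2.75), FReD (3.10 ± 0.55, -0.65 v -3.24), Taui1ph1 (3.00 ± 0.54, 3.36 v 0.57), P16 (2.89 ± 0.44, -0.30 v -3.01), P19 (2.83 ± 0.35, -0.21 v -2.85), Eve (2.65 ± 0.48, -0.34 v -2.76) and SmocL (2.12 ± 0.50). Downward moved Hox7 (-4.26 ± 1.00, -2.94 v 0.87), Ccdc83 (-3.35 ± 0.84, -3.15 v -0.27), Axndhc10h (-2.29 ± 0.53, -2.98 v -0.65), Map215prh (-2.18 ± 0.41, 0.81 v 2.92), Asphm2 (-2.10 ± 0.49), Dlgap5 (-1.66 ± 0.35), Trp53bp1 (-1.39 ± 0.34) and Nan2 (-1.38 ± 0.22, 3.42 v 4.91).

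It changed for 569 genes from mesenchyme blastula to early gastrula. The largest upward values are fitted against 0 UMIs in germline-like cells of mesenchyme blastula and are no bound on the change: Sat2_5 (12.55), Tmem26_5 (11.77), AnL1 (11.71), Tpase3 (11.26), Emx (11.20), DpdL (11.16), Tmprss5L (11.14) and Orc2 (10.98). Downward moved Brn1_2_4 (-4.93 ± 0.75, -1.60 v 2.93), Taui1ph1 (-4.13 ± 0.54, -0.67 v 3.36), Wscd1 (-2.63), Eea1 (-2.51), Rab3 (-2.48), Slc5a7_1 (-2.30) and Glyt (-2.07).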

How the results depend on the processing

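Settings of the named genes gave 8195 values, of which 7464 were the same, 657 weaker, 15 stronger and 59 reversed. The 8076 planned before the data were examined gave 7399, 617, 15 and 45, and the 119 added later 65, 40, 0 and 14. Limits are 2 libraries per stage with no record of separate cultures, 1 library at each early hour, uneven depth, class names that rest on a rule set after the clusters were seen, and a germline-like cluster of early gastrula that turns on the resolution. Where a setting moved a value, the cause was not tested. With an estimated correlation in camera, 0 lists passed in any of the 11 comparisons that had called lists (1, 5, 4, 4, 4, 2, 3, 2, 2, 3 and 4 lists at the preset correlation).

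With DESeq2 4386 genes changed from early to mesenchyme blastula, 4110 to early gastrula and 573 to late gastrula. It called 800, 1136 and 492 genes in the late gastrula contrasts (germline-like v other, skeletogenic-like v other, germline-like v skeletogenic-like), 92 and 108 in germline-like cells over time, and 19 and 259 in the interaction. With no filter beyond 1 count it was 71 and 213 in germline-like cells over time and 23 for the first interaction.

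Clusters from one random part of the UMIs gave 776 genes for germline-like v skeletogenic-like cells and 247, 1200 and 730 in the late gastrula contrasts. At resolution 2 it was 1011 for late gastrula germline-like v other cells, 96 in germline-like cells from mesenchyme blastula to early gastrula, and 27 and 16 in the interaction. With doublets left out, late gastrula germline-like v other cells gave 1205.

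A replicate block changed the counts to 6334, 5882 and 1241 for the stage steps, 192 and 290 in germline-like cells over time, and 32 and 438 in the interaction. That block pairs libraries of different stages by an assumed number. Without the library block the class contrasts gave 2931, 4646 and 1489 (stage kept in the fit), and 2259, 2416 and 1493 at late gastrula.

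Leaving out each library in turn gave 4964 to 7486, 4640 to 6867 and 565 to 1690 genes for the stage steps, and 1746 to 2779, 3040 to 4267 and 993 to 1506 for the class contrasts. It gave 116 to 280 and 187 to 387 in germline-like cells over time, and 7 to 56 and 245 to 575 in the interaction.

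The germline-like share was 0.631% at early blastula, 2.47% at early gastrula and 0.424% at late gastrula with 1000 or more genes per cell. It was 0.864% at early gastrula at resolution 2 and 1.40% at late gastrula at resolution 0.5. The skeletogenic-like share was 6.82, 2.48, 0.488 and 0.762% at the 4 later stages with 1000 or more genes, 6.94 and 0.994% at early blastula and late gastrula with doublets left out, and 13.2% at mesenchyme blastula at resolution 2.

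Thinned to 500 UMIs, Nan2 was in 1.28% of cells at 4 hpf, 19.5% at 6 hpf, 12.999% at 8 hpf and 11.1, 11.7, 5.28 and 3.91% at the later stages. Unthinned it was in 9.19, 46.7, 28.9, 28.3, 29.6, 14.99 and 9.92%. Vasa thinned to 500 was in 1.85% at 2 hpf, 1.35% at 6 hpf, 1.43% at 8 hpf and 1.64, 1.83, 1.58 and 1.34% at the later stages. Unthinned Vasa was in 7.08, 17.5, 8.99, 7.66, 9.88, 9.97, 8.45 and 4.80% from 2 hpf on.

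Cells with 1000 or more genes reversed Ef1a (-0.0697, reported 0.43) and Alx1_1 (0.20, reported -0.14) from early to late gastrula. For germline-like v other cells, no filter beyond 1 count took FoxY to -0.00151 (reported 0.16), and clusters from one random part of the UMIs took Alx1_1 to 0.14 (-0.36) and Seawi b to -0.24 (0.14). At late gastrula Seawi a (-0.07) went to 0.0947 with DESeq2 factors, 0.0822 with DESeq2 and 0.0280 at resolution 0.5. Resolution 0.5 also took Psmd3 to 0.00834 (-1.29), Abcb1b to 0.0622 (-1.86) and AnL3 to 3.76 (-1.54; 0.67 with clusters from one random part of the UMIs). For late gastrula germline-like v skeletogenic-like cells it took Atub13 to 0.32 (-2.49).

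In germline-like cells from mesenchyme blastula to early gastrula Seawi b (-0.00181) went to 0.00179 with DESeq2 factors, 0.0721 with no filter, 0.00243 at resolution 0.5 and 0.71 at resolution 2. Resolution 2 also reversed Ef1a (-0.0481), Btub3 (-0.33), Atub13 (-0.80), Hsp702A (-0.11), Hsp901 (-0.52) and Seawi a (0.16). In the interaction to early gastrula Msp130_1 (0.27) went to -0.13 with DESeq2 and -0.17 with a replicate block. Resolution 2 reversed Nk7 (-0.21), Hey4 (-2.19), Abcb4a (-0.0764), Atub13 (-0.0335), Tektin2 (-0.78), Hsp702A (-1.09) and Nan2 (0.19).

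Left-out libraries turned the sign of some genes that were not called. From early to mesenchyme blastula Vasa ranged from -0.16 to 0.00839 and Seawi b from -0.0207 to 0.15. From early to late gastrula Alx1_1 ranged from -0.64 to 0.0685 and Seawi b from -0.28 to 0.29. For germline-like v other cells FoxY ranged from -0.89 to 1.46 and Seawi b from -0.0504 to 0.25, and for skeletogenic-like v other cells Seawi a from -0.17 to 0.0154. In germline-like cells from early to mesenchyme blastula Seawi ranged from -0.52 to 0.43 (Seawi a) and -0.31 to 0.42 (Seawi b), and to early gastrula from -1.12 to 0.48 (Seawi b).

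In the first interaction the ranges were -0.25 to 0.76 for Alx1_1, -0.67 to 1.70 for Vasa, -0.96 to 8.92 for FoxY, and -0.0315 to 1.20 and -0.39 to 0.29 for the Seawi features. To early gastrula they were -8.88 to 0.68 for Msp130_1, -4.15 to 5.55 for FoxY, -8.66 to 2.01 for Alx1_1 and -0.20 to 1.12 for Seawi b.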

Other observations

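Germline-like cells had a very high Nan2 level at early blastula (10638 ± 194 CPM). Over early blastula, mesenchyme blastula and early gastrula together they had raised EhH4_65 histone, Cnot1 and Xrn1_1 transcripts. Cnot1 is the scaffold of the deadenylase complex and Cnot6L one of its catalytic subunits. Cnot1 was higher and Cnot6L lower in germline-like cells (1.41 ± 0.26 and -1.71 ± 0.29), each a single feature. Other features of the RNA decay list are named Cnot1_1, Cnot1_3 and Xrn1_1, and none of these others was called higher. The opposite moves are thus those of single features and not of all entries for the scaffold. Cnot1 was also higher in skeletogenic-like cells (0.73 ± 0.23), together with Xrn1_1 (3.42 ± 0.33), so a raised Cnot1 is not particular to the germline-like class.

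Hsp701A differed between the classes: a feature of that name was lower in germline-like cells than in skeletogenic-like cells (-1.92 ± 0.26; 909 ± 173 v 3197 ± 1583 CPM). Among ABC transporters Abca2 was lower in germline-like than in skeletogenic-like cells (-3.30 ± 0.37) and Abcc4a higher (0.80 ± 0.29). Abcc4a was also higher in germline-like than in other cells (1.40 ± 0.26). The mitochondrial genes Atp5c1 (0.70 ± 0.17) and Ndufa12 (-1.24 ± 0.18) moved in opposite directions in germline-like cells.

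At 8 hpf a cluster of 40 cells without a class name was led by Mysm1 and Nan2 and held 10.7% of the Nan2 UMIs at 11666 CPM, with a median of 957 UMIs. It is the nearest to the early blastula germline-like level, although the marker rule gave it no name. Skeletogenic-like cells had a Nan2 ratio to the whole library of 2.57 at early blastula, and 2823 CPM at 8 hpf. A shared pool of transcript made before the lineages part is a hypothesis that counts from separate embryos cannot test. Over all cells Nan2 stood at 21.6 CPM at 4 hpf and 655 at 6 hpf, so most of it appeared after 4 hpf.

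From 4 hpf to early blastula the most abundant feature was 1 with no gene name, at 5.23% of UMIs at 4 hpf, 16.4% at 6 hpf, 10.3% at 8 hpf and 5.41 and 4.96% in the early blastula libraries. What it encodes is not known from the feature tables.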
